A study of Homo sapiens with 3 samples.

How the data were processed

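Single-cell RNA sequencing was measured in 3 libraries of human cultured cardiac interstitial cells. Per the labels' protocols, heart tissue was digested with collagenase, cardiomyocytes were removed by centrifugation, cells were enriched on c-kit beads and grown to passage 5, and libraries were made with a droplet-based 3' kit with unique molecular identifiers (UMIs). Per the labels, LVAD1 and LVAD2 held LVAD-derived cells and 1 library held neonatal-derived cells. The labels do not say whether the LVAD libraries came from separate hearts. The p-values of single genes therefore measure the spread between these libraries, which may be technical in part.

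The deposited tables hold, for each gene and cell barcode, the natural log of 1 plus the UMIs of the gene per 10000 UMIs of the cell, 1 table per library. This unit was read from the values, since every cell summed to 10000 after the log was undone. Per the submitters' processing notes, Cell Ranger (version not given in the sources used here) and Seurat 2.3.4 were used with the genome build GRCh38.p3. Filters on cells or genes are not given in the sources used here, and no barcode in the deposited tables had 10% or more of its UMIs from mitochondrially encoded genes. The smallest non-zero value of each cell was 1 UMI, and with it 100% of the 7097745, 4486462 and 6932350 non-zero values of LVAD1, LVAD2 and the neonatal library came out as whole UMIs within 0.1. In 200 simulated cells the same step returned 0 wrong values among 942807.

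The tables listed 16982, 15972 and 16083 genes for LVAD1, LVAD2 and the neonatal library, 17959 in any and 14851 in all of them. A gene that a library's table did not list was set to 0 UMIs there. For the privacy of donors, XIST, TSIX, Y-linked genes and genes that follow common germline deletions were left out of every step. With 1 row that names no human gene, this left out 22 rows and kept 17937. IGF2, which the rule for named genes lists, was not analysed here. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which removed 7, 3 and 14 barcodes.

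UMIs were summed over the kept cells of each library. Library sizes were scaled by trimmed means of M-values with factors of 0.954, 1.00 and 1.05, genes with at least 10 UMIs in a library and 15 in all were tested, and log2 CPM (UMIs per 1e6) were taken with a prior of 2 UMIs, which is 0.057 CPM at the mean library size. Fold changes of genes with few UMIs are therefore understated. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05). A count model had been planned, but it was not used because the deposited unit is a log value. The fit set 2 libraries against 1 and had 1 residual degree of freedom, plus 3.33 from the shrinkage across genes. The neonatal library was assumed to vary like the LVAD libraries. On simulated counts for the same 3 library sizes, with 14619 genes tested and 50 changed genes per size, the fit called 0 of 50 genes at a log2 change of 1, 0 of 50 at 2, 18 of 50 at 3 and 44 of 50 at 5, with 2 unchanged genes called.

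Gene lists fixed before the data were examined (24 program lists and 13 cell type marker lists) were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists of each kind. The percentile of each list's median was taken among 10000 random lists of the same size matched on mean expression. On simulated data with 4 moved lists among 24, camera called 4 with the preset correlation and 0 with an estimated correlation, so with 1 residual degree of freedom the estimated form had little power. The simulated genes varied independently of each other. The simulation therefore cannot show whether the preset form calls too many lists whose genes move together. The p-values of camera with the preset correlation set the genes of a list against the other genes. They do not measure how a list varies between libraries, and a list that shifted in the single neonatal culture alone could be called too. Counts of genes at least 2-fold apart needed 10 CPM in a library and came with no test. The simulated counts with no group difference (100 draws) took each gene's spread from the limma prior, over all tested genes or over genes with at least 10 CPM. Each gene was drawn independently.

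Cells were normalized to 10000 UMIs, log-transformed and clustered without integration (scanpy 1.11.5, 2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.5). A cluster was named only from the marker lists. Scrublet called 2, 7 and 0 doublets, too few to be informative, and none were removed. Shares of cells with a UMI were compared after each cell was thinned to 8000 UMIs, which left out 149, 80 and 181 shallower cells. Intervals are exact Clopper-Pearson (shares) or exact Poisson (counts) at 95% and cover counting error only.

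Named genes followed a rule fixed before the data were examined. Among genes with an ordinary symbol, at least 50 CPM in a group and a difference of at least 1 on the log2 scale from the neonatal library in both LVAD libraries, the 12 largest positive and the 12 largest negative fold changes were taken, those past the test first. For each list, up to 4 members with at least 20 CPM on the side of the list's median and up to 2 on the other side were eligible. KIT, THY1, ENG, PDGFRA, PDGFRB, ACTA2, CDKN1A, CDKN2A, MKI67 and TOP2A were given whatever their values. Positions are from GENCODE 29 (GRCh38). Alternatives changed the cell filter, the depth per cell, the cell cycle state of the cells, the scaling, the low-count filter, the shrinkage, the inter-gene correlation, the cluster settings and the libraries used.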

Results

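Cultured cardiac interstitial cells are the non-muscle cells of heart tissue that grow out after enrichment on beads against c-kit, the receptor tyrosine kinase encoded by KIT. The series asks which features of biological age the transcriptome of such cells keeps in culture. The data were 3 single-cell libraries at passage 5, 2 from LVAD-derived cells (LVAD1 and LVAD2) and 1 from neonatal cells. LVAD1 held 1967 kept cells with 38501825 UMIs and a median of 18623 UMIs and 3659 genes per cell. LVAD2 held 958 cells with 30527771 UMIs and a median of 33160.5 UMIs and 5090 genes. The neonatal library held 1759 cells with 36275985 UMIs and a median of 20132 UMIs and 4110 genes. Values are CPM from the UMIs summed over each library. LVAD values are given as mean ± SD (n = 2), and the neonatal group had no replicate.

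The first comparison asked which genes differed between LVAD-derived and neonatal cells. The LVAD libraries carried high levels of several mRNAs that were scarce in the neonatal library. S100A4, a calcium-binding protein of motile and fibroblastic cells, stood at 629 ± 6.91 CPM in LVAD cells and at 7.87 CPM in neonatal cells, a log2 difference of 6.31 ± 0.22 (SE). ADIRF, an adipogenesis regulatory factor, stood at 545 ± 185 against 3.59 CPM, and the interferon-induced gene IFI27 at 192 ± 40.4 against 1.61 CPM. In the other direction MDFI, an inhibitor of myogenic transcription factors, stood at 5.08 ± 2.37 CPM in LVAD cells against 96.9 CPM in neonatal cells, and the sulfotransferase gene SULT1B1 at 8.87 ± 4.64 against 137 CPM.

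No gene passed limma's test at an adjusted p under 0.05 among 14968 tested. At an unadjusted p under 0.05 it gave 974 genes higher and 466 lower in LVAD cells. The smallest adjusted p in limma was 0.0617, for S100A4 (chromosome 1, 153543613 to 153550136). The count depended on the settings. Over 7695 genes with at least 10 CPM limma called 157 genes higher and 31 lower, and over cells with at least 1000 genes and at most 5% mitochondrial UMIs it called 81 and 11. Robust shrinkage gave 31 and 5, and the other settings ran from 51 and 7 down to 0 and 0.

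Further genes named by size were higher in both LVAD libraries. The urea transporter gene SLC14A1 stood at 92.8 ± 39.5 CPM against 0.581 CPM in neonatal cells, CYP1B1, a cytochrome P450 of steroid and xenobiotic metabolism, at 117 ± 60.7 against 1.66, and AKR1C3, a steroid-converting reductase with close paralogs, at 77.5 ± 11.6 against 1.95. IGFBP5, a secreted binding protein of insulin-like growth factors, stood at 118 ± 65.3 against 2.19 CPM, and ISLR, a secreted protein of stromal cells, at 52.8 ± 28.2 against 1.35. The alarmin IL33 stood at 54.1 ± 33.0 against 2.88 CPM, and SOST, a secreted WNT inhibitor, at 143 ± 4.25 against 10.9. DCN, a small proteoglycan of the fibroblast matrix, and RGS5, a regulator of G-protein signalling used as a pericyte marker, differed widely between the LVAD libraries. DCN stood at 288 CPM in LVAD1, 20.7 in LVAD2 and 2.297 in neonatal cells, and RGS5 at 367, 12.2 and 3.20 CPM. Adjusted p-values of these 12 genes in limma ran from 0.0617 (S100A4) to 0.571 (RGS5).

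The other genes named by size as lower in LVAD cells had neonatal levels from 50.6 CPM (HES4, a Notch-pathway repressor) to 961 CPM (C12orf75, 287 ± 94.1 in LVAD cells). KRT19, a keratin of simple epithelia and mesothelium, stood at 20.7 CPM in LVAD1, 2.78 in LVAD2 and 67.1 in neonatal cells. ECSCR, a cell-surface regulator first described in endothelium, stood at 45.2 ± 16.3 CPM against 187, and HAPLN1, a link protein of the hyaluronan matrix, at 48.8 ± 8.42 against 175. The cytokine gene IL11 stood at 15.7 ± 9.02 against 55.8 CPM, the small GTPase gene RAC3 at 26.1 ± 11.1 against 93.3, and the centromere protein gene CENPV at 30.4 ± 6.64 against 105. HES4, APCDD1L and TTYH3 stood at 15.4 ± 8.88, 13.7 ± 9.35 and 20.6 ± 2.68 CPM in LVAD cells against 50.6, 53.8 and 60.4 CPM. Adjusted p-values of these 12 genes in limma ran from 0.199 (MDFI) to 0.531 (KRT19).

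**Figure D1:**
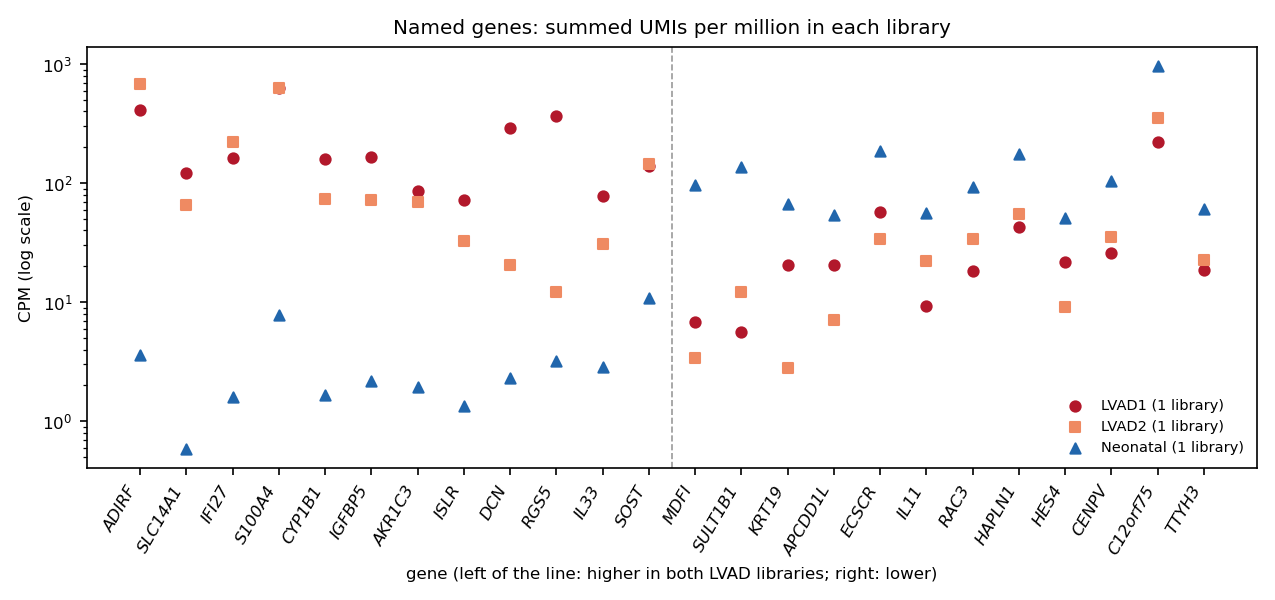
CPM on a log axis for the 24 genes named by size, 1 point per library (LVAD1, LVAD2 and neonatal). S100A4 stood at 624 and 634 CPM in the LVAD libraries and 7.87 CPM in the neonatal library, while DCN and RGS5 lay far apart between LVAD1 and LVAD2.

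Counted by size alone, 328 of 7695 genes with at least 10 CPM were at least 2-fold higher in both LVAD libraries than in the neonatal library, and 105 were at least 2-fold lower. Of these, 302 and 99 had an unadjusted p under 0.05 in limma. Because both differences share the neonatal library, some overlap arises by chance. With no group difference and the spread of all tested genes, simulation gave a mean of 66.9 genes higher and 66.2 lower (highest of 100 draws, 91 and 84). With the spread of genes with at least 10 CPM it gave 48.9 and 48.2 (62 and 64), and independent lists would share 33.9 and 9.2. The simulation drew each gene independently. Genes that move together would make such counts vary more, so the highest draws set no ceiling for chance. The neonatal library was not the sole one to stand apart: 347 genes were at least 2-fold from both other libraries in LVAD1 and 81 in LVAD2, against 433 in the neonatal library. With LVAD1 alone 653 genes were higher and 409 lower than in the neonatal library, and with LVAD2 alone 400 and 173.

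The bead-selected receptor gene KIT was scarce in all libraries at passage 5, at 0.817 CPM in LVAD1, 0.359 in LVAD2 and 1.93 in neonatal cells. KIT UMIs were found in 25 of 1967, 10 of 958 and 66 of 1759 cells, or 1.27%, 1.04% and 3.75%. After thinning these shares were 0.660%, 0.114% and 1.33%. No cell type that should lack KIT was at hand to set a background for these shares. The mesenchymal receptor genes ENG and PDGFRA were higher in both LVAD libraries, ENG at 383 ± 33.9 CPM against 139 and PDGFRA at 71.8 ± 23.4 against 20.7. PDGFRB stood at 13.9 ± 3.72 CPM against 9.69, and the surface glycoprotein gene THY1 at 16.3 ± 10.5 against 29.1. The cell cycle inhibitor genes CDKN1A and CDKN2A, both linked to senescence, stood at 124 ± 45.8 and 40.7 ± 10.2 CPM against 115 and 39.0, differences below the spread of the LVAD libraries. ACTA2, smooth muscle actin, stood at 278 CPM in LVAD1 and 32.3 in LVAD2, on either side of the neonatal 83.0 CPM. The adjusted p-values of these genes in limma were 0.256 or higher.

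The second comparison asked how groups of genes differed. Interferon-response genes lay higher in the LVAD libraries, with a median log2 difference of 1.92 in LVAD1 and 1.01 in LVAD2. Of 36 measured members 30 were higher in both LVAD libraries and 2 lower in both. The median was 1.55 in the fit, camera gave an adjusted p of 5.78e-12, and the adjusted p was 0.608 with an estimated correlation. Besides IFI27, IFI6 stood at 41.1 CPM in LVAD1 and 14.0 in LVAD2 against 4.41 in neonatal cells, IFITM2 at 306 and 255 against 90.4, and the immunoproteasome gene PSMB8 at 40.3 and 20.7 against 9.82. ISG15 stood at 99.9 and 72.6 against 93.3 CPM. Adjusted over the list alone 5 members passed (IFI27, IFI44L, IFITM2, IRF9 and XAF1), against 0 over all genes. Antigen-presentation genes (20 measured, none past the test over all genes or adjusted over the list alone) shared B2M, PSMB8, PSMB9 and TAP1 with this list and had medians of 1.90 in LVAD1 and 0.36 in LVAD2 (camera adjusted p = 0.000622, and adjusted p = 0.608 with an estimated correlation). B2M, the light chain of class I molecules, stood at 1972, 906 and 499 CPM in LVAD1, LVAD2 and neonatal cells.

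Inflammatory and secreted factors were also higher as groups. The NF-kappaB list had medians of 0.72 in LVAD1 and 0.50 in LVAD2, and the list of senescence-associated secreted factors 0.69 and 0.44. Their adjusted p-values in camera were 0.000336 and 0.000812, and each adjusted p was 0.608 with an estimated correlation. With no low-count filter the secreted factors were no longer called (camera adjusted p = 0.108). CCL2, a monocyte-attracting chemokine on both lists, stood at 1055 and 572 CPM against 84.6 in neonatal cells. HGF, hepatocyte growth factor, stood at 23.0 and 22.1 against 0.343 CPM, TNFAIP6 at 42.6 and 26.2 against 7.08, and FGF7 at 52.1 and 2.25 against 0.396. IL11 and CXCL6 went the other way, CXCL6 at 123 and 59.9 against 170 CPM. Adjusted over the list alone, 8 of the 40 secreted factors and 5 of the 26 NF-kappaB genes passed, and none over all genes. Immediate early genes (27 measured, none past the test over all genes or adjusted over the list alone) had smaller medians of 0.44 and 0.23 (camera adjusted p = 0.0110, and adjusted p = 0.608 with an estimated correlation), with EGR1 at 55.3 and 22.1 CPM against 3.80.

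Matrix genes lay higher in LVAD cells, most in LVAD1. The list of other matrix and matrix-processing genes had medians of 1.33 in LVAD1 and 0.54 in LVAD2, with 38 of 48 members higher in both (camera adjusted p = 7.17e-10, and adjusted p = 0.608 with an estimated correlation). LUM, a proteoglycan that binds collagen fibrils, stood at 90.7 and 9.11 CPM against 0.290, and FBLN2 at 181 and 79.7 against 18.0. HAPLN1 and MFAP2 went the other way, MFAP2 at 49.2 and 13.8 against 70.1 CPM. Adjusted over the list alone 11 members passed, and none over all genes. Fibrillar and network collagens (20 measured, 0 past the test over all genes or adjusted over the list alone) had medians of 1.01 in LVAD1 and 0.05 in LVAD2 (0.53 in the fit) and were not called (camera adjusted p = 0.0945). COL3A1 stood at 624 and 193 CPM against 43.2, whereas the basement membrane collagen COL4A1 stood at 141 and 140 CPM against 312.

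Among metabolic and stress lists, glycolysis and hypoxia genes had medians of 0.87 in LVAD1 and 0.49 in LVAD2 with 24 of 30 members higher in both, and lysosome and autophagy genes 0.92 and 0.29 with 20 of 25. The nuclear-encoded respiratory chain (37 measured) had medians of 0.32 and 0.28, and NRF2 targets (27 measured) 0.22 and 0.32. The adjusted p-values in camera were 6.43e-06, 0.000145, 0.00105 and 0.0138, and each adjusted p was 0.608 with an estimated correlation. PGK1, a glycolytic kinase, stood at 295 and 202 CPM against 113, the lysosomal protease gene CTSL at 90.3 and 62.8 against 25.6, NDUFB1 of respiratory complex I at 231 and 235 against 98.1, and HMOX1, heme oxygenase, at 24.5 and 31.9 against 13.2. No member of these 4 lists passed over all genes or adjusted over the list alone. The respiratory chain was no longer called over cells with at least 1000 genes and at most 5% mitochondrial UMIs (camera adjusted p = 0.0791). NRF2 targets were no longer called with no low-count filter (camera adjusted p = 0.051).

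Proliferation genes lay lower in LVAD cells. The S phase list had medians of -0.79 in LVAD1 and -0.20 in LVAD2 with 27 of 42 members lower in both, and the G2/M list -0.83 and -0.28 with 41 of 52. The DNA repair and chromatin list (31 measured) had medians of -0.71 and -0.24. In camera the adjusted p-values were 5.81e-07, 4.87e-10 and 0.000694, and each adjusted p was 0.608 with an estimated correlation. MKI67, the Ki-67 proliferation marker, stood at 56.2 and 80.3 CPM against 157, MSH6 of mismatch repair at 13.6 and 16.6 against 32.8, and the replication checkpoint gene CLSPN at 30.7 and 50.2 against 79.9. PCNA went the other way, at 41.8 and 54.4 against 39.8 CPM. TOP2A, a topoisomerase of dividing cells, stood at 72.1 and 90.3 against 97.1 CPM. Without cells that held TOP2A or MKI67 UMIs the S phase and G2/M lists had medians of -0.82 and -0.83. That setting used unthinned cells, in which such UMIs are found more often at greater depth. Median depths were 18623, 33160.5 and 20132 UMIs in LVAD1, LVAD2 and neonatal cells. The setting therefore cannot tell whether non-dividing cells differed. No member of these 3 lists passed over all genes or adjusted over the list alone.

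Contractile genes (26 measured) had medians of -0.18 in LVAD1 and -0.55 in LVAD2, and sterol biosynthesis genes (26 measured) -0.09 and -0.30. The adjusted p-values in camera were 0.000622 and 0.0172, and each adjusted p was 0.608 with an estimated correlation. CNN1, calponin of smooth muscle, stood at 8.25 and 0.719 CPM against 35.7, and TPM1, a tropomyosin, at 955 and 1040 against 1884. TAGLN, another actin-binding protein of smooth muscle, stood at 2689 and 956 CPM, on either side of 1228 in neonatal cells. No member of either list passed over all genes or adjusted over the list alone. Sterol genes were no longer called after thinning (camera adjusted p = 0.0537) or over genes with at least 10 CPM (camera adjusted p = 0.0613).

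The remaining program lists were not called. Their medians in the fit were 0.44 for heart field transcription factors (29 measured), 0.285 for mesenchymal surface markers (21), 0.27 for paracrine growth factors (34), 0.26 for cell cycle arrest and p53 targets (24) and 0.20 for the unfolded protein response (25). They were -0.18 for mitochondrially encoded genes (13), -0.245 for imprinted and early-growth genes (17) and -0.28 for TGF-beta and YAP response genes (22). Single libraries gave other values: in LVAD1 and LVAD2 the medians were -0.064 and -0.23 for mitochondrially encoded genes, 0.080 and -0.024 for imprinted genes, and -0.069 and -0.16 for TGF-beta and YAP genes. They were 0.53 and -0.027 for cell cycle arrest, 0.47 and 0.054 for paracrine factors, 0.40 and 0.29 for heart field factors, 0.38 and 0.22 for surface markers and 0.33 and 0.11 for the unfolded protein response. The adjusted p-values in camera ran from 0.0547 to 0.405. Within these lists TCF21, a transcription factor of the epicardial and fibroblast lineage, stood at 63.9 and 32.6 CPM against 3.70, and the RNA-binding protein gene IGF2BP1, active in fetal growth, at 1.12 and 1.80 against 25.7. HMGA2, a chromatin protein of early growth, stood at 55.5 and 104 against 222 CPM. No member passed over all genes. Adjusted over the list alone, TCF21, IGF2BP1, HGF among paracrine factors and ENG, MCAM, PDGFRA, ANPEP and MME among surface markers passed, and no member of the other 4 lists. Not all of these were higher in LVAD cells: IGF2BP1 was lower, and so was MCAM, at 2.61 and 1.57 against 24.7 CPM.

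**Figure D2:**
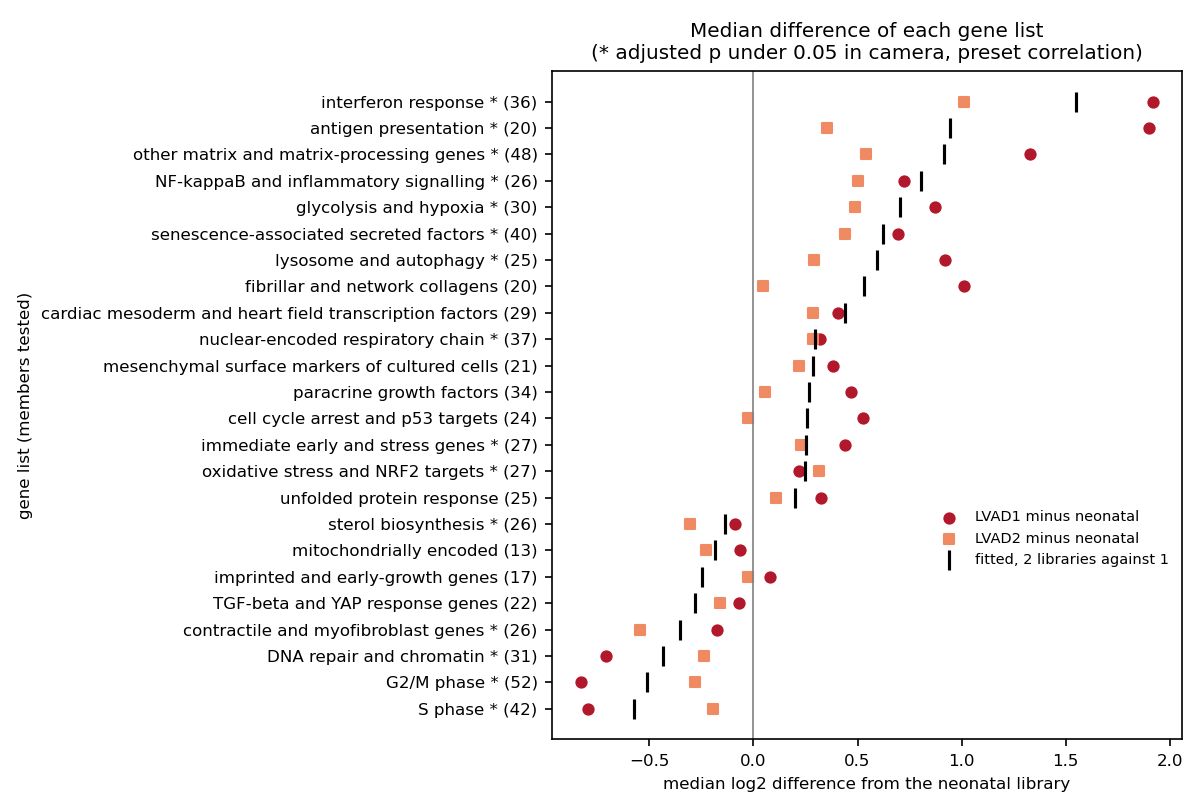
Median log2 difference from the neonatal library for each program list, 1 point per LVAD library and a line for the median in the fit, with the number of members tested in brackets and a star where the adjusted p in camera was under 0.05 with a preset correlation. The interferon list lay at 1.92 and 1.01 and the G2/M list at -0.83 and -0.28.

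Markers of cardiac cell types were set against the same libraries. Fibroblast markers had medians of 2.05 in LVAD1 and 1.39 in LVAD2, with 11 of 14 members higher in both (camera adjusted p = 7.73e-05, and adjusted p = 0.694 with an estimated correlation), while COL1A1 stood at 781 and 450 CPM against 705. Macrophage markers (3 measured of 12, median 1.77) and endocardial and lymphatic endothelial markers (5 measured of 7, median 1.56) were called higher. The adjusted p-values in camera were 0.00724 and 0.0261, and each adjusted p was 0.694 with an estimated correlation. These calls rest on few members, some of them scarce, and do not set a cell type. FCER1G of the macrophage list stood at 0.490 and 0.425 against 0.158 CPM, and CSF1R and MRC1 were too scarce to test. In LVAD1, PROX1 and LYVE1 of the other list stood at 1.525 and 0.436 CPM. With no low-count filter neither list was called (camera adjusted p = 0.200 and 0.289). CD68 on the macrophage list is also a lysosomal protein and stood at 23.0 and 21.8 against 6.55 CPM. Pericyte markers (8 measured, median 1.30), cardiomyocyte markers (4 measured, 1.34), smooth muscle markers (8 measured, -0.43), endothelial markers (12 measured, -0.61) and epicardial markers (7 measured, -0.87) were not called, with adjusted p-values in camera of 0.0568 or higher. The LVAD libraries differed here: medians in LVAD1 and LVAD2 were 2.68 and 0.0021 for cardiomyocyte, 0.22 and -1.13 for smooth muscle, 0.059 and -1.21 for endothelial, -0.74 and -1.41 for epicardial and 1.49 and 1.24 for pericyte markers. MCAM, on the pericyte list, stood at 2.61 and 1.57 CPM against 24.7. Schwann and neuronal markers (4 measured) had a median of -0.35 in the fit (-0.16 in LVAD1 and -0.11 in LVAD2) and a mean of 0.54, were not called, and turned to 0.15 to 0.23 in 3 settings. Lymphocyte, mast cell, adipocyte and erythroid markers had 1, 2, 2 and 0 measured members and were not tested. No marker passed over all genes. Adjusted over the list alone, 6 fibroblast, 5 pericyte, 2 macrophage, 2 endocardial and lymphatic, 1 endothelial and 1 Schwann and neuronal markers passed, and no smooth muscle, cardiomyocyte or epicardial marker. The pericyte markers that passed went both ways. ABCC9, NOTCH3 and NDUFA4L2 were higher in both LVAD libraries, and MCAM and CSPG4 lower. The endothelial marker, TIE1, was lower.

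The share of dividing cells was lowest in LVAD1 and highest in the neonatal library. After thinning to 8000 UMIs, 24.6% of LVAD1 cells (447 of 1818, interval 22.6 to 26.6%), 42.6% of LVAD2 cells (374 of 878, 39.3 to 45.9%) and 63.1% of neonatal cells (996 of 1578, 60.7 to 65.5%) held a TOP2A or MKI67 UMI. Without thinning the shares were 31.5%, 58.9% and 71.6%. By expression score 27.5%, 54.7% and 75.9% were in S or G2/M phase. No test was made of these shares. Free RNA between cells, which adds to such shares, was not measured.

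**Figure D3:**
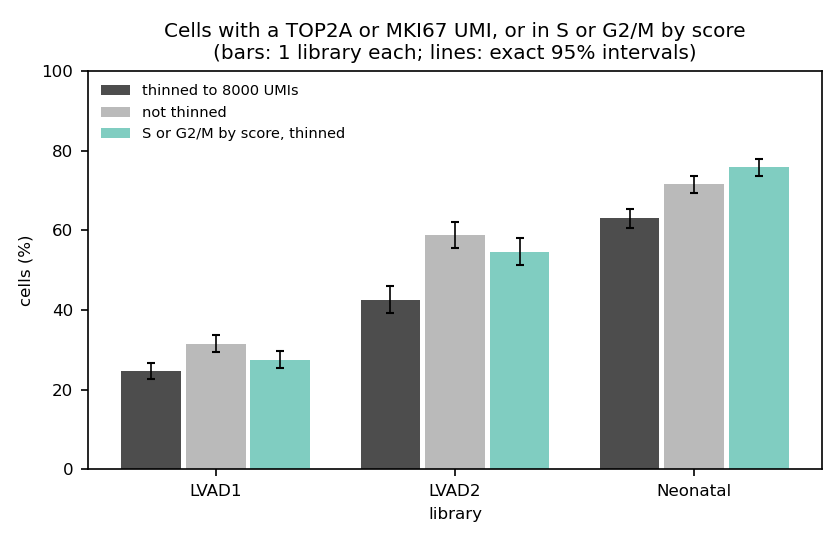
Percent of cells of each library with a TOP2A or MKI67 UMI, thinned or not, and percent in S or G2/M phase by score, with exact 95% intervals. The 3 measures rank the libraries alike, from LVAD1 (24.6% thinned) through LVAD2 (42.6%) to neonatal (63.1%).

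Clustering of the 4684 cells gave 10 clusters, nearly all of which belonged to single libraries. Clusters at least 80% from 1 library held 92.0% of cells (interval 91.1 to 92.7%). LVAD1 filled clusters 1, 4 and 6, LVAD2 clusters 3 and 9, and the neonatal library clusters 2, 5 and 7, so that a cluster here may be a library and not a cell type. Division genes led some clusters of each library, such as TOP2A in clusters 6 and 9 and ASPM and CENPF in cluster 5. Cluster 8 alone had no library with 80% of its cells, with 86, 124 and 167 barcodes and a median of 6390 UMIs. Cluster 10, with 20 LVAD1 cells, was endothelial-like, with 12 of 12 endothelial markers each found in at least 10% of its cells, that is in 2 cells or more. By the same measure 10 of 14 fibroblast markers were found in it, but its 10 leading genes included 2 endothelial and 0 fibroblast markers.

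**Figure D4:**
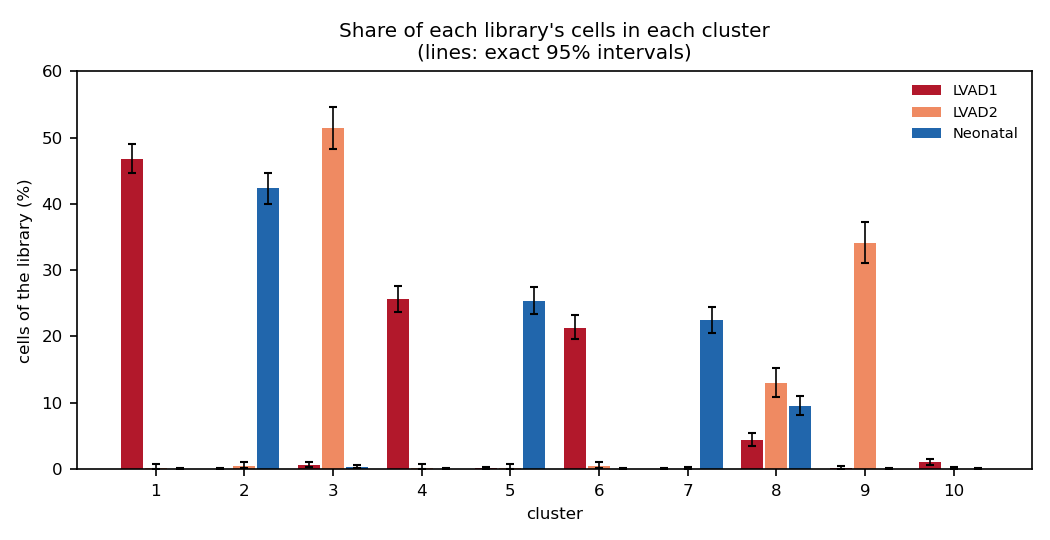
Percent of each library's cells in each of the 10 clusters, with exact 95% intervals. Most clusters came almost wholly from 1 library, such as cluster 1 with 46.8% of LVAD1 cells and cluster 3 with 51.5% of LVAD2 cells, while cluster 8 was spread over all of them.

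The last comparison set LVAD1 against LVAD2, with 1 library on each side and no test. The apolipoprotein gene APOE stood at 94.0 CPM in LVAD1 and 1.24 in LVAD2, TSTD1 at 50.1 and 1.04, the complement gene C7 at 55.5 and 1.47, and RGS5 at 367 and 12.2. LVAD2 was higher in MMP1, an interstitial collagenase, at 1205 CPM against 134, in PCDH9, a protocadherin, at 164 against 46.1, in C16orf74 at 58.8 against 16.7, and in ANKRD36C at 53.2 against 16.3. These are the 4 largest log2 differences each way among genes with at least 50 CPM in an LVAD library, a rule set after the values were seen. Over 7695 genes 461 were at least 2-fold apart, fewer than between LVAD1 and the neonatal library (1062) or LVAD2 and the neonatal library (573). DCN UMIs were found in 82.5% of LVAD1 cells, 29.4% of LVAD2 cells and 4.38% of neonatal cells, or 66.6%, 13.2% and 2.41% after thinning. In the endothelial-like cells of LVAD1, which should lack DCN, 2 of 20 (10.0%, median 12932 UMIs) held a UMI. No such background was measured for LVAD2 or the neonatal library.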

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

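A row named GFPCUSTOM, which matches no human gene, was read from the neonatal table and entered no comparison. It held 109 UMIs in 102 of 1773 barcodes, or 5.75% (exact interval 4.72 to 6.94%), with at most 3 UMIs in a barcode. It is listed because it lay above the 3 UMIs that a count of 0 allows and because no comparison used it. No row of that name was read from the LVAD tables.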

How the results depend on the processing

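Chosen after seeing the data were the alternatives over cells with at least 8000 UMIs, without cluster 8, with added pseudocounts and with equally weighted cells, those of the low-count filter for the gene lists, median of ratios scaling for the lists and the 2-fold counts, and all of those between LVAD1 and LVAD2. The planned DESeq2 test and the other planned count fits were not run, because the deposited unit is a log value, and robust shrinkage and median of ratios scaling were run in limma. Leaving out an LVAD library leaves 1 library against 1, with no residual degrees of freedom and no test. No paired analysis was possible because the groups share 1 replicate number. Against 0 genes higher and 0 lower, limma called 157 and 31 over genes with at least 10 CPM, 81 and 11 with at least 1000 genes and at most 5% mitochondrial UMIs per cell, 51 and 7 without cells that held TOP2A or MKI67 UMIs, 33 and 4 after thinning, and 31 and 5 with robust shrinkage. Median of ratios scaling, cells with at least 8000 UMIs and a pseudocount of 1 CPM each gave 1 gene higher and 0 lower. All barcodes, library size only, no low-count filter, a pseudocount of 5 CPM, equal weights and no cluster 8 gave 0 and 0. The fit over genes with at least 10 CPM tested fewer genes and had 9.92 prior degrees of freedom against 3.33. S100A4 passed in 8 of these fits, and ADIRF, IFI27, AKR1C3, HGF, SLC14A1 and SOST in 5 each. Scaling by library size only moved the median log2 difference of all genes by -0.095. The 328 and 105 genes at least 2-fold higher and lower in both LVAD libraries became 844 and 301 at 1 CPM and 113 and 19 at 50 CPM. Leaving out 1 LVAD library gave 400 to 653 higher and 173 to 409 lower, since 1 library then had to differ in place of both. Other settings kept both counts within 1.5 times. Between LVAD1 and LVAD2 the 461 genes became 1433 and 129 at 1 and 50 CPM. The 10 program lists called higher and 5 called lower became 0 and 0 with an estimated correlation. Of these 15 program lists, senescence-associated secreted factors (camera adjusted p = 0.108) and NRF2 targets (0.0510) were lost with no low-count filter, the respiratory chain with the stricter cell filter (0.0791), and sterol biosynthesis over genes with at least 10 CPM (0.0613) and after thinning (0.0537). With no low-count filter the macrophage (0.200) and the endocardial and lymphatic (0.289) marker lists were lost too. Lists that had not been called were gained in some settings: collagens in 4 (lowest adjusted p 0.00321, with the stricter cell filter), paracrine growth factors in 6, heart field factors in 3 and epicardial markers (lower) in 4. In 1 setting each, the imprinted (0.00869), mitochondrially encoded (0.0305) and smooth muscle (0.0201) lists were called lower without cells that held TOP2A or MKI67 UMIs, endothelial markers lower with the stricter cell filter (0.0184), and pericyte (0.0303) and surface (0.0364) markers higher over genes with at least 10 CPM. Medians of uncalled lists turned too: with the stricter cell filter Schwann and neuronal (0.15), TGF-beta and YAP (0.088) and imprinted (0.080), Schwann and neuronal also after thinning (0.21) and without TOP2A or MKI67 cells (0.23), imprinted also at 5 CPM (0.0034), and 4 lists with 1 LVAD library left out, whose medians per library differ in sign. No gene had passed the test, and 9 named genes turned direction in some setting. Without cells that held TOP2A or MKI67 UMIs the log2 differences of ACTA2, CDKN1A, CDKN2A, PCNA, TYMS and ZMAT3 turned to -0.51, -0.43, -0.098, -0.041, -0.25 and -0.16. With library size only those of CDKN1A, CDKN2A and TYMS turned to -0.036, -0.054 and -0.054. With the stricter cell filter those of TYMS, XRCC6, SQSTM1 and COL1A1 turned to -0.26, -0.072, 0.095 and 0.21. After thinning those of TYMS and SQSTM1 were -0.045 and 0.037, and with equal weights -0.056 and 0.048. The cycling shares of 24.6%, 42.6% and 63.1% became 31.5%, 58.9% and 71.6% without thinning and 27.5%, 54.7% and 75.9% by score. Their order held in each.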

Other observations

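Of the tests in this part, those of the mixture of cells (spread and gene levels), of the position of each library, of the mitochondrial share, of cells scored G1 and of what the shares of dividing cells allow were chosen after the results they bear on had been seen, as was the setting without cluster 8. The 20 endothelial-like cells of LVAD1 (cluster 10) carried PECAM1, the endothelial adhesion molecule, in 19 of 20 cells, against 2.88% of other LVAD1 cells, and the tight junction gene CLDN5 in 70.0% against 0.257%. The leading genes of cluster 10 also included TFF3 and the fatty acid binding protein gene FABP4. Stromal genes were low in these cells, COL1A2 at 22.4 CPM against 703 and COL3A1 at 32.0 against 599 in other LVAD1 cells. KIT UMIs were found in 3 of the 20 cells (interval 3.21 to 37.9%) and in 22 of 1947 other LVAD1 cells (1.13%, interval 0.709 to 1.71%). Within the main LVAD1 cells, cluster 1 was led by C7, RGS5, APOE and DCN, and cluster 4 by ADH1B, an alcohol dehydrogenase, the natriuretic peptide gene NPPB and NDUFA4L2, a hypoxia-responsive gene of mitochondria.

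Each library was placed between the other libraries, over genes at least 2-fold apart between those. LVAD2 had a median position of 0.528 (0 neonatal, 1 LVAD1; 1062 genes, 83.8% between), LVAD1 of 1.11 (0 neonatal, 1 LVAD2; 573 genes, 36.8% between) and the neonatal library of -0.19 (0 LVAD2, 1 LVAD1; 461 genes, 28.9% between), but among any 3 libraries 1 pair lies furthest apart and an unrelated library falls near the middle of genes chosen so, so this order shows no more than that LVAD1 and the neonatal library differed most. The position of LVAD2 was 0.524 after thinning and 0.533 without cluster 8. These values do not decide whether depth or cluster 8 set it, since neither step could move the position far. Thinning keeps the expected share of each gene in a cell's UMIs. Cluster 8 held 12.9% of LVAD2 cells, at low depth (median 8654 UMIs). For a mixture of LVAD1-like and neonatal-like cells, the spread over LVAD2 cells of the share of UMIs on LVAD1-higher genes decided nothing. It was 50.6% of the SD of such a mixture, against a bound of at most 50% set before the test. Gene levels argue against a mixture whose LVAD1-like cells hold the mean levels of LVAD1. Of 47 genes abundant in LVAD1 and scarce in neonatal cells, 38.3% had under 50% of the LVAD2 level that a mixture with 46.3% LVAD1 cells needs (RGS5 12.2 against 172 CPM, APOE 1.24 against 43.8). Another 4, such as ADIRF, lay above LVAD1. RGS5 and APOE are among the leading genes of cluster 1 of LVAD1, so a mixture with other LVAD1-like cells is not excluded. A biological difference between the cultures stays open and was not tested.

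Cluster 8 nearly lacked MALAT1, a nuclear-retained RNA, at 301, 170 and 316 CPM in LVAD1, LVAD2 and neonatal barcodes, against 22660, 14480 and 11340 CPM in the other clusters. Low depth alone does not bring such a loss. In LVAD1, LVAD2 and the neonatal library, 87, 24 and 41 cells of other clusters had at most 8000 UMIs. Their MALAT1 CPM was at least 35.2 times that of cluster 8 in each library. The clusters were formed from the same values, so the size of this ratio in part restates the clustering. Dying cells with leaking cytoplasm would have a higher mitochondrial share. The difference of cluster 8 from the others was -1.37 percentage points or further below 0 in each library. This does not exclude dying cells, since no deposited barcode reached 10% mitochondrial UMIs. Barcodes with a high share may have been removed before. Cytoplasmic RNA without nuclei is a candidate explanation: over 6 other nuclear-retained RNAs the median log2 ratio to the other clusters was -2.14, and -3.01 over the 5 with at least 3 UMIs expected, though PVT1 (-0.72) and JPX (-0.37) were little lower. The design gives no biological explanation, and none was tested.

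For the 433 genes at least 2-fold apart from the neonatal library in both LVAD libraries, 3 technical explanations were tested. For a lower share of dividing cells, the shares measured allow at most a 2.21-fold higher or 1.67-fold lower level in LVAD2. This holds even for a gene held by other or by dividing cells alone (widest ends of the intervals). Beyond this lay 90.8% of the genes (288 of 328 higher and 105 of 105 lower, thinned). The genes had been chosen at 2-fold or more in LVAD2, so the lower ones passed 1.67-fold almost by selection. The 90.8% is therefore no independent test. The bound says only that these shares alone allow no 2-fold lower level in LVAD2. The tests with bounds set before they were run did not decide. Among cells scored G1, 81.8% stayed (interval 77.8 to 85.3%, bound 80%). There the S phase list had a median of -0.36 against -0.76 in all thinned cells, but the G2/M list still had -0.55 against -0.63. Between neonatal cells scored G1 and the others, 18.0% differed 2-fold (interval 14.5 to 22.0%, bound 20%). The 88.5% that stayed without TOP2A or MKI67 cells decide nothing, since the S phase and G2/M lists differed more there (medians -0.82 and -0.83). After thinning 92.4% of the genes stayed, and without cluster 8 98.4% did. Neither share decides. Thinning keeps the expected share of each gene in a cell's UMIs, so levels summed over cells could hardly move. Cluster 8 held 4.37%, 12.9% and 9.49% of the cells of LVAD1, LVAD2 and the neonatal library, at low depth. Its removal could hardly undo most 2-fold differences. It stays open, and was not tested, whether these genes follow the LVAD and neonatal groups or the single neonatal culture. Both make the same split of the libraries. Even a group difference could not be assigned to age, since any other difference between LVAD-derived and neonatal-derived cells would make that split too.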
